A study of Arabidopsis thaliana with 12 samples.

How the data were processed

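RNA from whole roots of Arabidopsis thaliana seedlings was measured on 12 single-channel Affymetrix arrays, in 4 groups of 3 samples. The groups were wild type (Col-0) and the tga1/tga4 double mutant, named for a pair of bZIP transcription factor genes, each given 5 mM KNO3 or, as the control salt, 5 mM KCl for 2 h. Before that, seedlings had been kept for 14 days in hydroponic medium in which ammonium succinate (0.5 mM) supplied the nitrogen and sucrose (3 mM) the sugar, under 16 h light and 8 h dark at 22 °C, and they were 15 days old at the treatment. The labels call the replicates independent and biological without saying what separated them, so the p-values measure the spread between these samples, which may be partly technical.

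The deposited table gave 1 value per probe set and sample on a log2 scale, and the authors' background correction, normalization and summary method were not given in the sources used here. The scale was settled from the hybridisation controls. The control cre exceeded bioB by 6.24 on average over the 12 samples, against 6.06 for log2 and 4.2 for the natural log of the ratio of their nominal concentrations of 100 and 1.5 pM. The slope of the 4 controls on log2 nominal concentration was 1.00. Sample medians lay between 2.21 and 2.41. The median standard error was 0.164 on the log2 scale for a difference between groups of 3 samples and 0.232 for the interaction.

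The table held 22810 probe sets, of which 64 controls were left out and 22746 were tested. A gene table supplied with the data named genes for 14016 of the 22746, with 1 gene for 13513 probe sets, several for 503 and none for 8730. The single-gene probe sets covered 13355 genes, and symbols and loci follow the TAIR10.1 annotation, from which no coordinates were used. A gene with several probe sets was represented by the one with the highest mean over all samples. Probe sets without an entry are given by their identifier only, and whether any of them measures a gene disrupted in the mutant was not analysed here.

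A linear model with 1 mean per group was fitted to all 12 samples with limma 3.58.1 in R 4.3.3. Contrasts were taken for KNO3 minus KCl in wild type, KNO3 minus KCl in the mutant, mutant minus wild type under each salt, the interaction (the nitrate response of the mutant minus that of wild type) and the average nitrate response. Moderated tests without an intensity trend were two-sided and adjusted by the Benjamini-Hochberg method over the 22746 probe sets, at an adjusted p of 0.05 with no fold threshold. The ratio of the mutant to the wild-type response was the median over probe sets called for the average response with an average change of at least 0.5 on the log2 scale.

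The model was tested on simulated data of 22746 probe sets, 200 of them changed, in 5 runs. For a nitrate contrast, changes of 0.5, 1 and 2 on the log2 scale were recovered in 8.96%, 73.4% and 97.9% of cases, with 5.49% false calls. For the interaction the shares were 1.49%, 34.3% and 91.8%, with 6.01% false calls. The simulated samples were independent, while samples here that shared a salt and a replicate number deviated together. These shares therefore need not hold for these data.

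Of 24 gene lists written from general knowledge, with 321 genes, 48 genes were measured under a name, and 7 lists had the 3 members needed for a test. These were the lists for nitrate transport, reductant supply, nitrate regulators, CC-type glutaredoxins, auxin and lateral roots, root hairs and reference genes. A further 30 families were taken from the gene symbols after the values had been received and before any group difference was computed. The pattern defining chloroplast-encoded genes was corrected, and a mitochondrial family dropped, after differences had been seen. Lists of extensins, low-oxygen genes and heat-shock genes were compiled from general knowledge after members had been noticed among changed or deviating genes. Each list was tested with camera (limma, preset correlation 0.01), adjusted by Benjamini-Hochberg over 37 lists within a contrast, with an estimated correlation and fry beside it. The p-values of the lists chosen afterwards are unadjusted. Those lists include the noticed members, so their p-values do not measure chance. On simulated lists of 15 genes shifted by 0.5, camera called 100% of shifted and 2.89% of unshifted lists. The simulated genes were independent, so these shares do not hold for lists whose genes vary together. Estimated correlations were, for example, 0.294 for expansins and 0.378 for root hair genes.

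The contrasts, the tests, the 24 lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named the 8 highest and 8 lowest changes among called single-gene probe sets of each contrast and up to 2 members per direction of each list. It also listed TGA1, TGA4 and the main genes of nitrate uptake and reduction, which are not analysed here by name. Probe sets called in a genotype contrast or the interaction, and remaining called members of lists, were added after their values were seen.

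Replicate numbers come from the labels. Whether they paired samples was examined by correlating, across the brighter 50% of probe sets, the deviations of samples from their group means, and principal components used the same probe sets. Alternatives covered an additive replicate block, each of the 12 samples left out in turn, quantile, cyclic loess and median scaling, removal of the dimmest 40% of probe sets, an intensity trend with robust variances, analysis of variance per probe set without moderation, array quality weights, a fit to only the samples compared, stricter thresholds and 1 probe set per gene. A pseudocount alternative was meant for linear values and was not run. Blocks of the samples sharing a salt and a replicate number, random (statmod 1.5.0) or fixed, and the omission of both KNO3 samples numbered 3 were chosen after seeing the data. Each contrast was also computed for other splits of the same samples, all 10 where 6 samples were compared and 100 drawn with a fixed seed where 12 were.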

Results

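The arrays measured root transcripts in 12 samples, 3 for each combination of genotype and salt. The design asks how roots respond to 2 h of nitrate and whether that response differs in the tga1/tga4 double mutant. Salt was the main source of difference between the samples, with 54.7% of the variance of the brighter 50% of probe sets on a first component that separated all 6 KNO3 samples from all 6 KCl samples. The second component, with 15.1%, set the KNO3 samples numbered 3 of both genotypes apart from the other KNO3 samples. The KCl samples numbered 3 lay on the same side, at -14.8 in wild type and -20.8 in the mutant. The other KCl samples lay between -6.9 and 11.4. Within a salt, wild-type and mutant samples of the same number deviated from their group means together. The correlations across the brighter 50% of probe sets, which are not independent replicates, were 0.53, 0.34 and 0.50 under KCl and 0.28, 0.64 and 0.73 under KNO3 for numbers 1, 2 and 3. Numbers 1 and 2 did not pair KCl with KNO3 samples in this way, with correlations from -0.14 to 0.14 within a genotype. For number 3 these correlations were weak but all positive, 0.225 in wild type and 0.229 in the mutant. Across genotypes they were 0.241 and 0.204 for number 3.

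In wild-type roots, nitrate raised a set of genes strongly. AT2G48080 went from 1.14 ± 0.32 to 7.61 ± 0.25 (log2, mean ± SD, n = 3 each), a rise of 6.47 with a standard error of 0.20. AT4G32950, a member of the protein phosphatase 2C family, rose by 6.03, AT5G10210 by 5.90 and PGM (AT1G78050), a phosphoglycerate mutase, by 5.71. AT3G07350, the HPP-family membrane protein gene AT5G62720 and AT5G19970 rose by 5.70, 4.49 and 4.42. In all of these the 3 KNO3 samples lay above the 3 KCl samples, and the largest adjusted p was 3.09e-07 (limma, Benjamini-Hochberg). The KCl means of these genes, except PGM, lay at 1.01 to 1.95, below the medians of their samples and not shown to exceed background, so the size of these changes is uncertain. The genes that fell changed less. The largest decreases among named genes were those of AT1G64590 (-3.45), the F-box gene AT2G32560 (-3.36), AT5G01210 (-2.55), SUFE2 (-2.47), of a family that acts in iron-sulfur cluster assembly, and the MYB-type factor MYBC1 (-2.45), with adjusted p from 8.15e-07 to 0.00173 (limma) and all 3 KNO3 samples below the KCl samples.

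Genes that supply reductant were among those that rose in wild type. All 3 measured members of that list changed, over all probe sets and adjusted over the list alone. The 6-phosphogluconate dehydrogenase genes AT5G41670 and AT1G64190, of the oxidative pentose phosphate pathway, rose by 4.28 ± 0.18 and 2.69 ± 0.11 (log2 change ± SE, n = 3 per group). AT3G02360, of the same enzyme family, fell by 0.43 (limma adjusted p = 0.022). The list rose by camera (adjusted p = 0.00104, Benjamini-Hochberg), a call lost with an estimated correlation (adjusted p = 0.233 with an estimated correlation). The decrease of AT3G02360 was no longer called without wild type KCl replicate 1, 2 or 3 (adjusted p = 0.0532, 0.0548 and 0.0885) or without wild type KNO3 replicate 1 or 3 (0.0997 and 0.0604).

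Of the 4 measured nitrate regulators, 3 rose in wild type, and the same number passed when adjusted over the list alone. AT1G68670 (HHO2), AT1G25550 (HHO3) and AT3G25790 (HHO1), which encode related GARP-type transcription factors, rose by 4.0 ± 0.26, 3.81 ± 0.25 and 3.18 ± 0.84. NRG2 (AT3G60320) had a change of -0.09 and did not pass. The list rose by camera (adjusted p = 2.68e-05, Benjamini-Hochberg), and this call held with an estimated correlation (adjusted p = 0.0375 with an estimated correlation). AT3G25790 was near the threshold (limma adjusted p = 0.0487), and its call ended without any 1 of 9 samples, which were the wild-type samples except KNO3 replicate 2, the mutant KCl samples and mutant KNO3 replicate 1, with adjusted p from 0.0619 to 0.156. AT2G43760 (CNX6), which acts in the synthesis of the molybdenum cofactor used by nitrate reductase, rose by 1.43 ± 0.15 (limma adjusted p = 0.000112).

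Some genes of cell wall families rose in wild type. EXPA7 and EXPA18, expansins expressed in root hair cells, rose by 1.69 ± 0.30 and 2.23 ± 0.34, which made 2 of 3 measured root hair genes, also adjusted over the list alone, while TRY changed by 0.25 and did not pass. The root hair list rose by camera (adjusted p = 0.00154, Benjamini-Hochberg; adjusted p = 0.236 with an estimated correlation). Of 14 expansins 2 rose and 12 did not pass, against 3 higher and 1 lower adjusted over the list alone, and the list was not called (camera adjusted p = 0.175). Of 10 xyloglucan endotransglucosylase genes 3 rose, XTH20 by 2.37 ± 0.43 among them, against 4 adjusted over the list alone, and this list was not called either (camera adjusted p = 0.175). The list passed without wild type KNO3 replicate 3 (camera adjusted p = 0.0269). Of 15 CC-type glutaredoxin genes 1 rose, also adjusted over the list alone, AT3G62930 by 1.1 ± 0.21, and the list was just above the threshold (camera adjusted p = 0.0505; adjusted p = 0.706 with an estimated correlation). With the preset correlation it passed without wild type KCl replicate 2, wild type KNO3 replicate 2 or 3 or any 1 of the mutant KNO3 samples, with adjusted p from 0.00605 to 0.0488.

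Few nitrate transport, auxin and reference genes passed in wild type. Of 3 measured nitrate transport genes of 20 listed, NRT2.5 stood at -0.59, AT2G26690 at -0.81 and AT1G68570 at 0.64, and 0 passed (limma; 1 at an unadjusted p under 0.05; camera adjusted p = 0.786). Of 4 auxin and lateral root genes, with LBD16 at -0.27 and GH3.3 at -0.53, 0 passed (limma; 0 at an unadjusted p under 0.05; camera adjusted p = 0.569). Of 4 reference genes, with AT2G28390 at -0.27 and AT4G34270 at 0.03, 0 passed (limma; 1 at an unadjusted p under 0.05; camera adjusted p = 0.569). Adjusted over each list alone, 0 passed in these 3 lists. Among 11 genes of the NPF family, which includes nitrate transporters, AT1G72125 rose by 1.12 and AT3G21670 fell by 1.88 (limma adjusted p = 0.0137 and 0.0495), against 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.475). These calls ended without any 1 of 3 and 9 samples, with adjusted p up to 0.0637 and 0.162 (limma).

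Single members of larger families also responded in wild type. The cytochrome P450 gene CYP78A9 rose by 3.69 ± 0.45, among 28 family members of which 1 rose, 2 fell and 25 did not pass, against 2 higher and 2 lower adjusted over the list alone. The glutathione transferase gene GSTU21, the ubiquitin-conjugating enzyme gene UBC18 and the sugar transporter gene SWEET16 rose by 1.48, 1.49 and 1.35, each the only riser among 11, 13 and 16 family members, while 1 ubiquitin-conjugating enzyme gene, UBC29, fell by 0.87. The glycosyltransferase gene UGT71C3 fell by 1.35, while 2 of the 51 members of its family rose, UGT84A4 by 1.26 among them. TRM21 fell by 1.13, the only 1 of 15. Adjusted over each list alone, 1, 2, 2 and 2 genes were higher and 0, 1, 0 and 1 lower among glutathione transferase, ubiquitin-conjugating enzyme, sugar transporter and glycosyltransferase genes, and 0 higher and 2 lower in the TRM family. Among 23 TRICHOME BIREFRINGENCE-LIKE genes TBL25 rose by 0.97, TBL38 fell by 1.02 and 21 did not pass, against 3 higher and 2 lower adjusted over the list alone. In all of these the 3 KNO3 samples lay on the changed side, with adjusted p from 0.000115 to 0.0104 (limma), and none of the families was called by camera, with adjusted p from 0.153 to 0.879. The sugar transporter list passed without wild type KNO3 replicate 2 and the TRM list without wild type KNO3 replicate 3 (camera adjusted p = 0.0183 and 0.0373).

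Over all probe sets, limma with Benjamini-Hochberg adjustment called 1253 in wild type, 755 higher and 498 lower with nitrate, and 717 of them changed at least 2-fold. Probe sets that name 1 gene made up 611 of the 1253. Of the 20 called probe sets with the largest increase, 12 had no gene name, so the named genes cover part of the response. The count was 815 without wild type KNO3 replicate 1.

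In the double mutant, the same genes led the response. AT2G48080 rose by 6.46 ± 0.20, AT3G07350 by 5.85 ± 0.17, AT4G32950 by 5.83 ± 0.32, AT5G10210 by 5.82 ± 0.15 and PGM by 5.59 ± 0.24 (log2 change ± SE, n = 3 per group), each with all 3 KNO3 samples above the KCl samples and a largest adjusted p of 4.11e-07 (limma). AT5G19970 and AT5G62720 rose by 4.71 and 4.60. As in wild type, the KCl means of all but PGM lay below the medians of their samples. The largest decreases were those of AT1G64590 (-3.55), AT2G32560 (-2.95), SUFE2 (-2.6), AT4G17670 (-2.41) and AT1G55790 (-2.39), with adjusted p from 5.93e-07 to 0.00112 (limma). The reductant genes AT5G41670 and AT1G64190 rose by 4.30 and 2.82 and AT3G02360 fell by 0.51, so that all 3 passed, also adjusted over the list alone (camera adjusted p = 0.00171; adjusted p = 0.268 with an estimated correlation). Of the 4 nitrate regulators 3 rose, also adjusted over the list alone, AT1G25550 by 3.84, AT1G68670 by 3.84 and AT3G25790 by 3.74 (camera adjusted p = 9.28e-07; adjusted p = 0.0176 with an estimated correlation). The call of AT3G25790 (limma adjusted p = 0.0224) ended without any 1 of the mutant samples except KNO3 replicate 2, with adjusted p from 0.0574 to 0.0759. AT2G43760 rose by 1.48 ± 0.15 and AT3G62930 by 1.29 ± 0.21, the only 1 of 15 CC-type glutaredoxin genes that rose, also adjusted over the list alone (camera adjusted p = 0.17).

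Among other groups in the mutant, the root hair genes did not pass, while EXPA8 and the autophagy list were called lower. EXPA7 and EXPA18 had changes of 0.54 ± 0.30 and 0.73 ± 0.34, and 0 of the 3 root hair genes passed, over all probe sets or adjusted over the list alone (limma; 0 at an unadjusted p under 0.05; camera adjusted p = 0.222). EXPA8 fell by 2.15 ± 0.26 (limma adjusted p = 0.000349). The nitrate transport, auxin and lateral root and reference gene lists were not called, with 0 members past the threshold over all probe sets (limma; camera adjusted p = 0.422, 0.422 and 0.826). Of these, 1 nitrate transport gene passed adjusted over its list alone. Among autophagy genes 1 of 11 fell, ATG8D by 0.61, against 3 adjusted over the list alone, and the family was lower by camera (adjusted p = 0.0165; adjusted p = 0.687 with an estimated correlation). In wild type 1 of 11 fell as well, also adjusted over the list alone, ATG8F by 0.80 (limma adjusted p = 0.0444, lost without any 1 of 10 samples), with a family median of -0.16 (camera adjusted p = 0.225). Without wild type KCl replicate 2 the wild-type family response was called (camera adjusted p = 0.0419). Under KCl the genotype difference of the family was not called (0.161) but passed without either of 2 samples (0.000424 and 0.0233). The interaction of the family was not called (camera adjusted p = 0.416), though it passed without wild type KCl replicate 1 (0.0118). The mutant call is therefore not a difference shown between genotypes. The family call was lost without tga1 tga4 KCl replicate 1 or 2 (adjusted p = 0.0874 and 0.0677), and the call of ATG8D, at an adjusted p of 0.0487, without any 1 of the wild-type KNO3 samples, the mutant KCl samples, mutant KNO3 replicates 1 and 2 and wild type KCl replicate 3 (limma, 0.0615 to 0.168). In all, limma called 1165 probe sets in the mutant, 722 higher and 443 lower, 687 of them at least 2-fold. The count was 720 without tga1 tga4 KNO3 replicate 1 and 1822 with array quality weights.

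The responses of both genotypes were compared directly. AT5G41670, at 4.28 and 4.30, changed by almost the same amount, and the 95% confidence interval of the difference ran from -0.53 to 0.57. Of the probe sets called in both genotypes, 550 rose in both, against 24.0 for independent lists, 265 fell in both, against 9.70, and 0 moved in opposite directions by the limma calls. A further 438 were called in wild type only and 350 in the mutant only, and 415 and 338 of these had the same sign in the other genotype. A call in 1 genotype alone does not show a difference between them. The correlation of both responses across the 22746 probe sets, which are not independent replicates, was 0.857 (Spearman's rho 0.571). Part of it can come from shared handling, since same-numbered samples of both genotypes deviated together. Over 2015 probe sets the median ratio of the mutant to the wild-type response was 1.01, with quartiles of 0.821 and 1.23. Computed from the samples of each replicate number, the ratio was 0.972, 0.969 and 1.00 (SD 0.0174). Because same-numbered samples of both genotypes deviated together, this SD can understate the uncertainty of the ratio. With 1 sample left out, the ratio ran from 0.911 to 1.08. Of these omissions, 8 moved it by more than that SD.

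**Figure D1:**
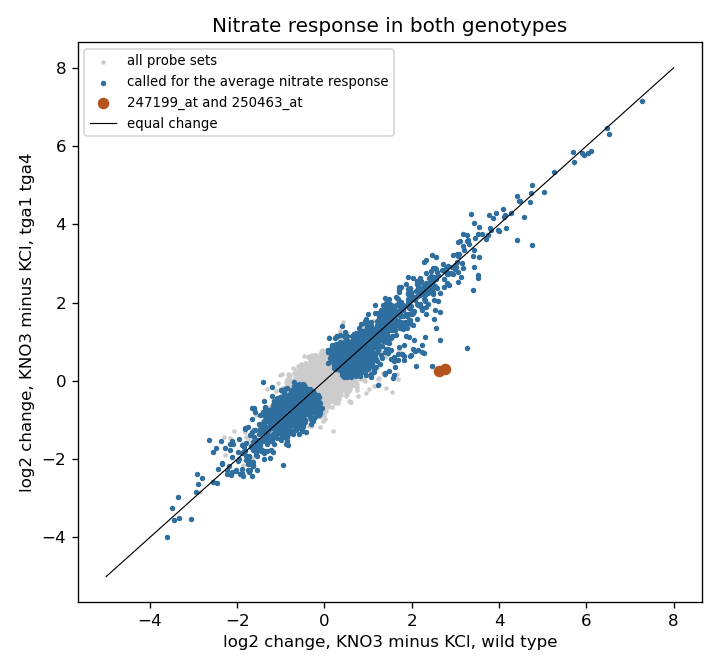
Each point is a probe set, with its log2 change under nitrate in wild type on the horizontal axis and in the tga1/tga4 mutant on the vertical axis, and the line marks equal change. Most probe sets called for the average nitrate response lie along the line, though calling on the average favours probe sets that changed alike in both genotypes. Probe sets 247199_at and 250463_at, with wild-type changes of 2.76 and 2.63, lie far below the line.

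Averaged over both genotypes, nitrate changed 2560 probe sets by limma, 1323 up and 1237 down. This fit treats same-numbered samples of both genotypes as independent, which for the average tends to give SE and p that are too small, and the random salt and number block, chosen after seeing the data, called 1930, 1036 up and 894 down. AT5G10210 rose by 5.86 ± 0.10, PGM rose by 5.65 ± 0.17 and MYBC1 fell by 2.35 ± 0.20 (log2 change ± SE, n = 6 per salt). For the average, 2 of the 15 CC-type glutaredoxin genes rose, also adjusted over the list alone, and the list was called (camera adjusted p = 0.0338; adjusted p = 0.757 with an estimated correlation). That call was lost without wild type KCl replicate 1 or 3, wild type KNO3 replicate 1, tga1 tga4 KCl replicate 1 or 2 or tga1 tga4 KNO3 replicate 3 (adjusted p = 0.103, 0.0669, 0.0675, 0.0876, 0.0544 and 0.0833). The nitrate regulator, reductant and root hair lists rose as well (camera adjusted p = 1.07e-05, 0.00501 and 0.00865), with 3, 2 and 2 members that rose, and adjusted p of 0.0301, 0.422 and 0.439 with an estimated correlation.

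Under the control salt, few probe sets differed between genotypes, and none of those called had a gene name. Probe set 247199_at stood at 4.62 ± 0.46 in wild type and 1.1 ± 0.35 in the mutant (log2, mean ± SD, n = 3 each), and 250463_at at 2.67 ± 0.24 and 0.62 ± 0.21. Whether any of these measures a gene disrupted in the mutant was not analysed here. Probe set 260002_at went from 5.75 ± 0.09 to 4.03 ± 0.31 and 260851_at from 2.47 ± 0.22 to 1.07 ± 0.11. In each the 3 mutant samples lay below the 3 wild-type samples, with adjusted p of 0.000178, 0.000445, 0.00766 and 0.0188 (limma, Benjamini-Hochberg). Except in 260002_at, the mutant values lay below the sample medians and are not shown to exceed background, so the size of these differences is uncertain. These 4 probe sets, chosen because their values passed, were the only ones called, all lower in the mutant, while 1068 had an unadjusted p under 0.05, against 1137.3 by chance. Because same-numbered samples went together, p-values of this unpaired model tend to be too large for genotype and interaction, though not for every probe set, and low counts do not show that the genotypes were alike. The call of 260002_at ended without wild type KCl replicate 1 or 2 or tga1 tga4 KCl replicate 3 (limma adjusted p = 0.0527, 0.0752 and 0.0693), with analysis of variance (0.177) and with only the samples compared (0.0921). That of 260851_at ended without wild type KCl replicate 1 or 2 or tga1 tga4 KCl replicate 2 or 3 (limma adjusted p = 0.0558, 0.144, 0.119 and 0.0962), with an additive replicate block (0.0603), without both KNO3 samples numbered 3 (0.058), with analysis of variance (0.247) and with only the samples compared (0.109).

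Root hair genes and expansins stood higher in the mutant under KCl as lists, though no single gene passed. EXPA18 was at 4.12 ± 0.90 in the mutant and 2.90 ± 0.20 in wild type, and EXPA7 at 3.8 ± 0.79 and 2.72 ± 0.08 (log2, mean ± SD, n = 3 each). Of the 3 root hair genes 0 passed over all probe sets and 2 adjusted over the list alone, with a median difference of 1.07 (limma; 2 at an unadjusted p under 0.05; camera adjusted p = 0.0104; adjusted p = 0.826 with an estimated correlation). Among 14 expansins 12 had a positive difference, 0 passed over all probe sets and 2 adjusted over the list alone (limma; 4 at an unadjusted p under 0.05; camera adjusted p = 0.00131; adjusted p = 0.826 with an estimated correlation). Both list calls were lost without wild type KCl replicate 1 (camera adjusted p = 0.112 and 0.106) or tga1 tga4 KCl replicate 2 (0.112 for both). The lists of xyloglucan endotransglucosylase and TRICHOME BIREFRINGENCE-LIKE genes were not called (camera adjusted p = 0.919 and 0.734). EXPA7 and EXPA18 belong to both called lists, and each passed on its own without tga1 tga4 KCl replicate 1 (limma adjusted p = 0.0146 and 0.00803).

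With samples of the same salt and number fitted as a fixed block, chosen after seeing the pairing, limma called 18 probe sets under KCl in place of 4, and 2123 had an unadjusted p under 0.05. All 4 were among the 18. The random version of this block called 6, all lower in the mutant, so that none of the calls higher in the mutant passed with it. The 10 that were higher in the mutant included EXPA9 by 0.93 ± 0.125, the extensin gene HRGP1 by 0.97 ± 0.133 and AT1G52070 by 1.39 ± 0.187 (log2 difference ± SE, n = 3 pairs; limma adjusted p = 0.0337 each). The probe set of HRGP1 is marked as able to cross-hybridise. The 8 that were lower included AT5G15950 at -0.97 ± 0.14 and 252534_at at -1.96 ± 0.185 (limma adjusted p = 0.046 and 0.00292). The mutant KCl values of 252534_at, 0.70 to 1.00, lay below the sample medians and are not shown to exceed background. Without a block the count was 18 without tga1 tga4 KCl replicate 1, 14 higher and 4 lower in the mutant. The overlap of these calls with those of the fixed block was not counted. The count was 2 without wild type KCl replicate 2 or tga1 tga4 KCl replicate 3.

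Under nitrate, the same probe sets were the ones that differed by genotype, except 260851_at. Probe set 247199_at stood at 7.38 ± 0.20 in wild type and 1.4 ± 0.26 in the mutant, 250463_at at 5.30 ± 0.20 and 0.87 ± 0.16, and 260002_at at 6.31 ± 0.19 and 4.39 ± 0.31 (log2, mean ± SD, n = 3 each). The adjusted p were 2.27e-07, 1.54e-07 and 0.0025 (limma), and in each the 3 mutant samples lay below the wild-type samples. The call of 260002_at ended with analysis of variance (adjusted p = 0.0802) and with only the samples compared (0.0954). These 3 were the only probe sets called, and 397 had an unadjusted p under 0.05, fewer than the 1137.3 expected by chance. Probe set 260851_at differed by -0.01 under nitrate. With nitrate it changed by -1.396 in wild type (limma adjusted p = 0.000312). Its KNO3 values in both genotypes lay below the sample medians and are not shown to exceed background. A genotype difference under nitrate therefore could not be judged for this probe set. With the fixed block 252534_at was called as well, at -1.81 ± 0.185 (limma adjusted p = 0.00637), which made 4, and 1092 had an unadjusted p under 0.05. The mutant KNO3 values of 247199_at, 250463_at and 252534_at lay below the sample medians, with the same limit as under KCl. Of the 3 root hair genes, 14 expansins and 4 nitrate regulators 0 passed, also adjusted over each list alone (limma; 0 at an unadjusted p under 0.05), and none of the 37 lists adjusted together was called by camera, with adjusted p of 0.872, 0.291 and 0.872 for these 3. The lists compiled afterwards include the members that were noticed, so their p-values do not measure chance. Of these lists, the extensins were lower in the mutant (camera unadjusted p = 1.58e-07; p = 0.0164 with an estimated correlation). The low-oxygen genes were higher only with the preset correlation (camera unadjusted p = 0.000266; p = 0.281 with an estimated correlation), and reversed without wild type KNO3 replicate 3 (unadjusted p = 0.218). For the expansins, with a median of -0.16, the camera adjusted p with the preset correlation was 0.0429 with the fixed block and 0.0221 without tga1 tga4 KNO3 replicate 3, against an adjusted p of 0.983 with an estimated correlation.

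The interaction tested whether nitrate responses differed between genotypes. Probe set 250463_at rose by 2.63 ± 0.16 in wild type and changed by 0.25 ± 0.16 in the mutant, a difference of -2.38 ± 0.23 (log2 ± SE, n = 3 per group; limma adjusted p = 0.00731). It was the only probe set called, and 683 had an unadjusted p under 0.05, against 1137.3 by chance. The mutant values of 250463_at ran from 0.43 to 1.05, below the sample medians, so they are not shown to lie above background, and the difference mainly reflects the wild-type response. Probe set 247199_at had a difference of similar size, 2.76 ± 0.24 in wild type against 0.30 ± 0.24 in the mutant, and was not called (-2.46 ± 0.34; adjusted p = 0.145). Its mutant values, 0.79 to 1.64, also lay below the sample medians, with the same limit. With the fixed block both passed, with adjusted p of 0.00191 for 247199_at and 0.00515 for 250463_at, so that 2 were called, and 1473 had an unadjusted p under 0.05. The call of 250463_at ended without wild type KCl replicate 3 or tga1 tga4 KNO3 replicate 1 (limma adjusted p = 0.051 and 0.0506), and 247199_at was called without wild type KCl replicate 1 (0.0426).

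The root hair and expansin lists, which share EXPA7 and EXPA18, had a negative interaction by camera with the preset correlation. The 3 root hair genes had a median interaction of -1.15, with EXPA18 at -1.50 ± 0.48 and EXPA7 at -1.15 ± 0.42, and 0 passed over all probe sets and 2 adjusted over the list alone (limma; 2 at an unadjusted p under 0.05; camera adjusted p = 0.0168; adjusted p = 0.652 with an estimated correlation). All 14 expansins had a negative interaction, with a median of -0.27, and 0 passed over all probe sets or adjusted over the list alone (limma; 4 at an unadjusted p under 0.05; camera adjusted p = 0.000195; adjusted p = 0.719 with an estimated correlation). EXPA8 and EXPA9 stood at -1.21 ± 0.37 and -1.17, and EXPA8 was lower with nitrate in both genotypes, at -0.94 in wild type, which did not pass (limma adjusted p = 0.0646), and -2.15 in the mutant. The wild-type change of EXPA8 was called with an additive replicate block, a random salt and number block, array weights and without both KNO3 samples numbered 3 (limma adjusted p = 0.0361, 0.0419, 0.018 and 0.0317). The rise of EXPA9 in wild type, 1.25 with an adjusted p of 0.0702, was called with the additive and random blocks (limma adjusted p = 0.00803 and 0.038). The lists of xyloglucan endotransglucosylase and TRICHOME BIREFRINGENCE-LIKE genes were not called (camera adjusted p = 0.831 and 0.38). The TRICHOME BIREFRINGENCE-LIKE list passed without tga1 tga4 KCl replicate 1 (camera adjusted p = 0.0392). The root hair call was lost with an additive replicate block (adjusted p = 0.0537), without both KNO3 samples numbered 3 (0.127), and without wild type KCl replicate 1, wild type KNO3 replicate 1 or 2, tga1 tga4 KCl replicate 2 or 3 or tga1 tga4 KNO3 replicate 3 (adjusted p = 0.0648, 0.0583, 0.0558, 0.0566, 0.0556 and 0.133). The reductant and nitrate regulator lists had camera adjusted p of 0.926 and 0.772 for the interaction, with 0 members called by limma (0 at an unadjusted p under 0.05).

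**Figure D2:**
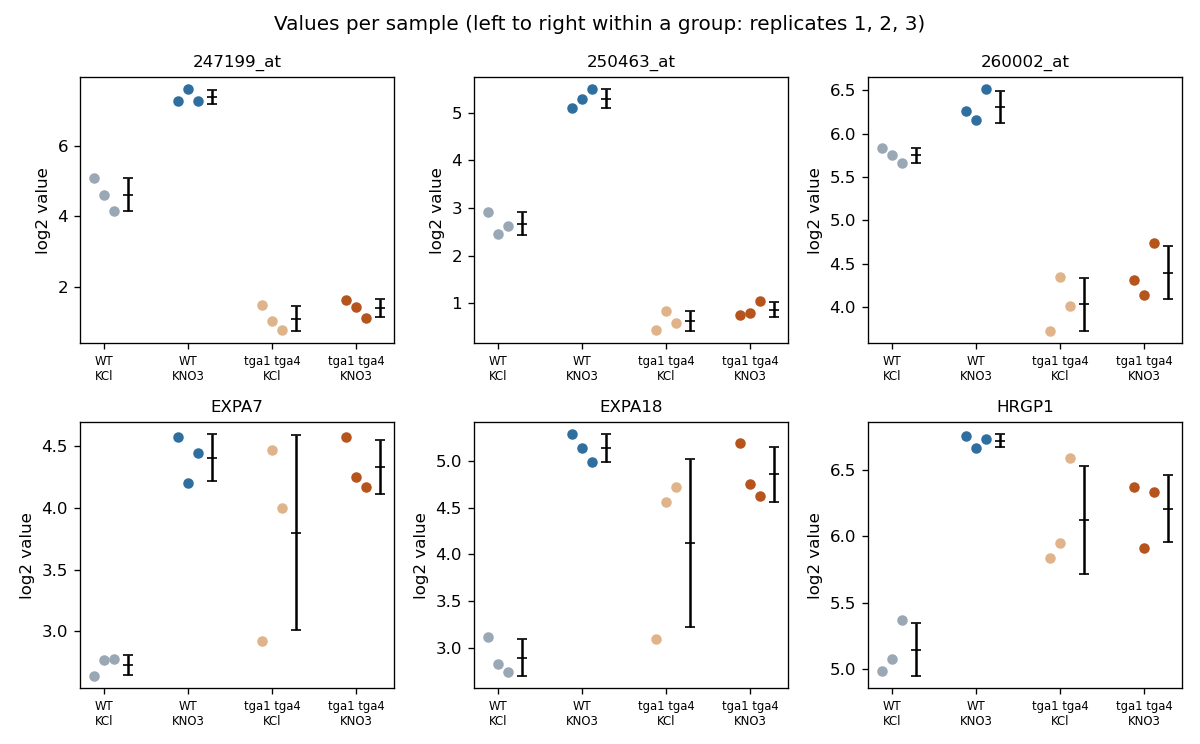
Points are log2 values of single samples in the 4 groups of 3, in the order of replicates 1 to 3, and bars give the mean and SD, for 3 probe sets without a gene name and 3 named cell wall genes. The mutant samples of 247199_at and 250463_at stay low under both salts, and the mutant KCl samples of EXPA7 and EXPA18 spread more widely (SD 0.79 and 0.90) than the other groups. The probe set of HRGP1, the other named gene, is marked as able to cross-hybridise.

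Responses could be compared only within the precision of 3 samples per group. Of the 793 probe sets with an average change of at least 2-fold, 363 (45.8%) had a 95% confidence interval for the interaction within 1 log2 unit either way, while 49 had an unadjusted interaction p under 0.05 (limma). This was 6.18%, against 3.00% of all probe sets in the same fit, and with the fixed block it was 122, or 15.4% against 6.48%. For the remaining probe sets a difference of 1 log2 unit or more is therefore not ruled out. Smaller differences remain possible in the 363 as well. AT1G64190, at 0.14 ± 0.16, and AT5G41670, at 0.02 ± 0.25, were among the genes with an interval within 1 log2 unit either way.

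Genes of the low-oxygen and heat-shock responses, lists compiled after members had been noticed, differed between replicates under nitrate. AT2G17850 stood at 8.24, 8.62 and 5.36 in wild-type KNO3 samples 1, 2 and 3 and at 8.17, 8.56 and 6.40 in the mutant samples, and AT3G10020 at 5.83, 5.80 and 3.86 and at 5.89, 6.79 and 4.18. The heat-shock gene AT1G53540 stood at 3.99, 3.39 and 1.14 and at 2.85, 5.18 and 1.45. Of the 22 low-oxygen genes 3 fell with nitrate in wild type, AT4G17670 (-2.13), AT5G44730 (-1.67) and AT5G47060 (-0.90), and 2 in the mutant, AT4G17670 (-2.41) and AT5G47060 (-1.02), against 5 and 2 adjusted over the list alone (limma). In wild type the call of AT5G44730 ended without any 1 of 3 samples and that of AT5G47060 without any 1 of 4, with limma adjusted p up to 0.0738 and 0.0716. The latter also ended without both KNO3 samples numbered 3 (0.0612), and in the mutant without tga1 tga4 KNO3 replicate 1 (0.0507). The list was lower with nitrate in wild type (camera unadjusted p = 8.57e-06, median -0.50) and in the mutant (unadjusted p = 0.00591, median -0.21), calls lost with an estimated correlation (p = 0.196 and 0.408), and the mutant call was lost without tga1 tga4 KNO3 replicate 3 (p = 0.452). Under KNO3 the list was higher in the mutant than in wild type, with 18 of 22 genes positive and a median of 0.26 (camera unadjusted p = 0.000266; p = 0.281 with an estimated correlation), and for the interaction the median was 0.23 (unadjusted p = 0.0422; p = 0.538 with an estimated correlation). Both calls ended without tga1 tga4 KNO3 replicate 2 (camera unadjusted p = 0.498 and 0.884), and without wild type KNO3 replicate 3 both directions reversed (unadjusted p = 0.218 and 0.212). That of the interaction also ended without wild type KCl replicate 1, tga1 tga4 KCl replicate 1 or tga1 tga4 KNO3 replicate 1 (camera unadjusted p = 0.241, 0.108 and 0.148) and without the dimmest 40% of probe sets (0.17). Of the 8 heat-shock genes 0 passed in either genotype (limma; 1 and 0 at an unadjusted p under 0.05), and the list was lower in wild type (camera unadjusted p = 0.00779, median -1.28; p = 0.31 with an estimated correlation), a call lost without wild type KNO3 replicate 3 (p = 0.249). In the mutant the heat-shock median was -0.70 (camera unadjusted p = 0.0861; p = 0.504 with an estimated correlation), with an unadjusted p of 0.0261 with the additive block. The mutant list also passed without either of 2 single samples (camera unadjusted p = 0.000356 and 0.0159). For genotype under KNO3 and the interaction, with medians of 0.31 and 0.29, the unadjusted p were 0.103 and 0.241 by camera, 0.00359 and 0.0331 with the fixed block, and 0.526 and 0.646 with an estimated correlation. For genotype under KNO3 it was 0.0486 with the additive block (camera, unadjusted p). Single samples also decided both. Genotype under KNO3 passed without any 1 of 3 samples (camera unadjusted p from 3.63e-05 to 0.0193). The interaction passed without either of 2 (0.00158 and 0.031).

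**Figure D3:**
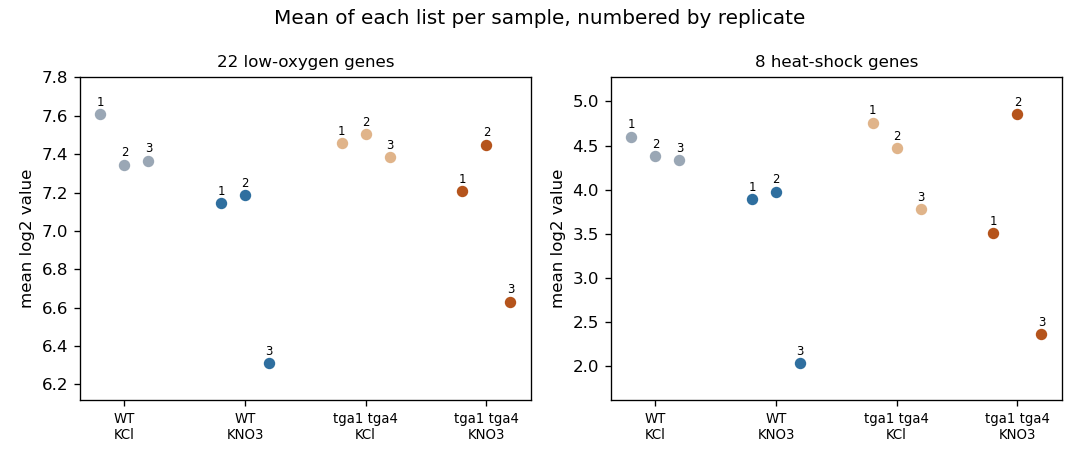
Points are single samples, numbered by replicate, with the mean log2 value over 22 low-oxygen genes or 8 heat-shock genes on the vertical axis and the 4 groups on the horizontal axis. The KNO3 samples numbered 3 of both genotypes have the lowest means, 6.31 and 6.63 for low-oxygen genes and 2.04 and 2.37 for heat-shock genes.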

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

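The tests of cell wall genes below, the extensin list and the salt and number block were chosen only after the results were seen, and the splits of the samples were planned.

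Probe set 250463_at responded to nitrate in wild type (2.63 ± 0.16) and not past the threshold in the mutant (0.25 ± 0.16), a difference between genotypes of -2.381 (log2, n = 3 per group; limma adjusted p = 0.00731). Its mutant means were low under both salts, 0.62 ± 0.21 and 0.87 ± 0.16, with 6 of 6 mutant samples below every wild-type sample. The mutant values, 0.43 to 1.05, lie below the sample medians and are not shown to exceed background, so the difference reflects the wild-type rise and does not measure a lost response. The adjusted p was 0.00515 with the fixed salt and number block, 0.17 with analysis of variance per probe set, 0.051 without wild type KCl replicate 3 and 0.0506 without tga1 tga4 KNO3 replicate 1. Probe set 247199_at had the same form, -2.46 ± 0.34, and passed in the fit with that block (adjusted p = 0.00191). Whether either measures a gene disrupted in the mutant was not analysed here, and no explanation was tested.

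Splits of the samples gave a measure of chance for each count of called probe sets (limma). For the average nitrate response 1 of 100 splits, the real one with 2560 probe sets, gave as many, and the highest other count was 7. Most other splits mixed KCl with KNO3 samples, which widens the spread and lowers their counts, and same-numbered samples were not independent. Chance is therefore not excluded by this share, the smallest that 100 splits can give. The nitrate comparisons of 6 samples have the same limit. For the interaction 8 of 100 splits gave at least the real count of 1, so chance was not excluded. The highest other count was 201, in a split that kept the samples numbered 3 together, which points to a structure of the samples by number. Among the 18 splits that, like the real one, parted every pair of same-numbered samples, the highest other count was 5. The fixed salt and number block, a separate fit for which no splits were counted, called 2. For comparisons of 6 samples the 10 splits are too few for a share under 0.05. There, 1 of 10 splits gave as many as the real 1253 in wild type, with 0 as the highest other, and 1 of 10 as many as the 1165 in the mutant, again with 0. For genotype under KCl 1 of 10 gave as many as the real 4, with 1 as the highest other. Under KNO3 2 of 10 gave as many as the real 3, and the other was a split that kept the samples numbered 3 together, with 21 probe sets. Among the 4 splits parting every pair, in the same fit as the real 3, the highest other count was 0. The fixed block, for which no splits were counted, called 4.

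The root hair and expansin lists had a lower nitrate change in the mutant by camera with the preset correlation, with a median interaction of -1.15 for 3 root hair genes (camera adjusted p = 0.0168) and -0.266 for 14 expansins (adjusted p = 0.000195), which share EXPA7 and EXPA18. Over the alternatives, the adjusted p of the root hair list ranged up to 0.883 and that of the expansins up to 0.883, both with fry. EXPA7 rose from 2.72 ± 0.08 to 4.41 ± 0.19 in wild type and stood at 3.8 ± 0.79 and 4.34 ± 0.22 in the mutant (log2, mean ± SD, n = 3). The extensin HRGP1 rose from 5.15 ± 0.20 to 6.72 ± 0.05 in wild type (limma adjusted p = 0.000427) and stood at 6.12 ± 0.41 and 6.21 ± 0.25 in the mutant, with an interaction of -1.49 (adjusted p = 0.957). Its probe set carries a mark of cross-hybridisation, so part of this signal may belong to similar genes. Of 11 extensins 10 had a negative interaction, with a median of -0.76 (camera unadjusted p = 1.34e-09; p = 0.00808 with an estimated correlation), and 0 passed over all probe sets (limma; 6 at an unadjusted p under 0.05, and 5 adjusted over the list alone). The extensin list includes the members whose change led to it, so its p-values do not measure chance. With nitrate the list was higher in wild type, with a median of 0.45 and 3 genes that rose, HRGP1, AT4G08410 and AT5G06630, against 4 higher and 1 lower adjusted over the list alone (camera unadjusted p = 0.019; p = 0.213 with an estimated correlation). In the mutant it was lower, with a median of -0.19 and 1 gene that fell, AT1G26250, against 2 adjusted over the list alone (camera unadjusted p = 0.00794; p = 0.164 with an estimated correlation). Each of these calls also ended without any 1 of 2 samples (camera unadjusted p up to 0.0793 and 0.198). The extensins stood higher in the mutant under KCl, with a median of 0.37 (camera unadjusted p = 6.27e-05; p = 0.0497 with an estimated correlation), and lower under KNO3, with a median of -0.45 (unadjusted p = 1.58e-07; p = 0.0164 with an estimated correlation).

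For EXPA7, EXPA18 and the 11 extensins together, 13 genes with a median interaction of -1.14, the tables argue against a single sample as the cause, since the median nearest 0 over the 12 omissions was -0.814, without tga1 tga4 KCl replicate 2. Signal shared between similar extensin probe sets stays open. The 7 extensins whose probe sets carry no mark of cross-hybridisation had a median of -0.489 (bootstrap SE 0.256, over genes that are not independent), which lies beyond the bound of -0.2 by more than 1 SE, the margin first set, but not by 2 SE, the margin taken after the values were seen because the genes are dependent, and the 4 marked ones had a median of -1.37. Uneven root hair content of the mutant KCl samples also stays open, because their means over the 13 genes were 3.97, 4.32 and 4.66, an SD of 0.347, against 0.3 in mutant KNO3 and 0.107 and 0.0929 in the wild-type groups. Within numbers the mutant differed from wild type by 0.091, 0.627 and 0.796 under KCl and by -0.188, -0.341 and -0.601 under KNO3, 1 sign in each salt. The KNO3 differences would not come from the KCl samples, but mutant KNO3 samples spread as well, and 3 pairs, in genes chosen for the pattern, are too few to exclude it. A lower response of these genes to nitrate in the mutant, from a level that may already be raised under KCl, remains open as an untested biological explanation.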

How the results depend on the processing

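The salt and number blocks, the omission of both KNO3 samples numbered 3 and the omissions of single samples for lists were chosen after seeing the data. Of 182 values for the comparisons under an alternative, 139 stayed within 1.5 times the reported count or, for the ratio, within the spread between replicates. The others follow. With limma, the count of 1253 for nitrate in wild type became 763 with analysis of variance, 640 at an adjusted p of 0.01, 717 with a 2-fold change required, 581 with 1 probe set per gene and 815 to 1326 with 1 sample left out. The 1165 in the mutant became 736, 638, 687 and 552 in the same order, 1822 with array quality weights and 720 to 1221 with 1 sample left out. The 2560 for the average response became 1415 at 0.01, 793 with a 2-fold change and 1244 with 1 probe set per gene. Fewer features were tested with 1 probe set per gene, and stricter thresholds call fewer by construction. For other changes the cause was not tested. The 4 probe sets differing by genotype under KCl became 2 with analysis of variance or only the samples compared, 0 with 1 probe set per gene, 18 with the fixed block, and 2 (without wild type KCl replicate 2 or tga1 tga4 KCl replicate 3) to 18 (without tga1 tga4 KCl replicate 1). The 3 under KNO3 became 0 with 1 probe set per gene, since the called probe sets have no gene name. The 1 for the interaction became 2 with an additive replicate block, median centring, trend and robust variances, array quality weights or the random or fixed block, 0 with analysis of variance or 1 probe set per gene, and 0 (without wild type KCl replicate 3 or tga1 tga4 KNO3 replicate 1) to 2 (without wild type KCl replicate 1 or wild type KNO3 replicate 2). The ratio of 1.01 became 1.04 without both KNO3 samples numbered 3, and 0.911 to 1.08 with 1 sample left out. Without wild type KNO3 replicate 3 the low-oxygen list reversed, with a camera (limma) unadjusted p of 0.218 for genotype under KNO3 and 0.212 for the interaction, and with any 1 sample left out these ranged from 1.91e-10 to 0.498 and from 1.08e-05 to 0.884. Of 10467 values for named genes, 9965 kept their side of the threshold, 445 lost a call, 57 gained one and 0 reversed. Of 4884 for lists, 4732 kept theirs, 100 lost a call, 50 gained one and 2 reversed. A reversal was counted only where the main fit or the alternative made a call. Values called in neither fit count as kept, whatever their direction. Where 1 of 3 samples was left out, the rest were assumed to vary like the other groups. Scaling alternatives moved the median change of all probe sets by at most 0.0824 in size. A fit to only the samples compared gives no value for the interaction, the average or the ratio, the fixed block none for nitrate contrasts, and the pseudocount was not run. Signal over background could not be judged from summarised values, and 13600 probe sets remained without the dimmest 40%.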

Other observations

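The test of low-oxygen and heat-shock genes was chosen only after the result was seen, and the test of scaling was planned before.

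Chloroplast-encoded genes, whose pattern was corrected after differences had been seen, were lower with nitrate as a list. In wild type psbK and psaB stood at -1.14 and -1.16, and of 69 genes 0 passed (limma; 3 at an unadjusted p under 0.05, and 0 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 0.0133; adjusted p = 0.706 with an estimated correlation). In the mutant 0 of 69 passed (limma; 2 at an unadjusted p under 0.05), with a median of -0.17 (camera adjusted p = 0.0337; adjusted p = 0.827 with an estimated correlation). The wild-type call was lost without wild type KCl replicate 1 or 2 or KNO3 replicate 1 (adjusted p = 0.312, 0.0717 and 0.345), and the mutant call without tga1 tga4 KCl replicate 1 or 2 or KNO3 replicate 1 or 3 (adjusted p = 0.454, 0.106, 0.44 and 0.0623).

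The KNO3 samples numbered 3 of both genotypes deviated from the other KNO3 samples in the same way, with a correlation of 0.726 across the brighter 50% of probe sets, which are not independent replicates. Scaling between arrays as the whole cause is argued against, since the correlation was 0.727 after cyclic loess. Low-oxygen genes such as AT2G17850 were lower in those samples. Deviations from the group means, which include the samples numbered 3, were averaged over both samples. Of the 19 low-oxygen genes not noticed beforehand, 18 had a negative mean deviation. Their median was -0.467, at percentile 0.01 of random lists of similar level, the smallest that 10000 lists can give. All 8 heat-shock genes were lower, with a median of -1.56 and percentile 0.01, and the 3 not noticed beforehand had a median of -0.482 and percentile 0.56. The random lists drew genes independently, while the estimated correlation was 0.527 within the low-oxygen and 0.78 within the heat-shock list. Lists of genes that vary together can reach extreme percentiles in any deviating sample, so the percentiles do not measure chance.

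A candidate explanation is a condition shared by both samples numbered 3 that lowered low-oxygen and heat-shock expression, which the percentile of 0.01 leaves open, though the pattern was found and tested on the same data. Nothing in the labels tells a shared culture from shared processing, and no biological explanation was tested. The hybridisation controls differed by number in both salts. The control bioB stood at 4.56 to 5.89 in the samples numbered 3, against 3.82 to 4.46 in the others. The control bioC stood at 6.75 to 8.23, against at most 6.65. Arrays numbered 3 thus differed under KCl as well, and a difference in processing is not told apart from a condition of the KNO3 samples. Without both samples, limma called 1036 probe sets in wild type, of which 895 were among the 1253, and 1112 in the mutant, of which 896 were among the 1165.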
